A study of Corynebacterium glutamicum with 9 samples.

How the data were processed

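Transcript levels were measured by RNA sequencing in 9 libraries of Corynebacterium glutamicum, labelled ATCC 13032, grown in a 5 L fermentor with dissolved oxygen (DO) held at 0%, 30% or 50%. Each DO level had 3 libraries, all from samples taken after 20 h of fermentation, early in the stationary phase, and quenched in liquid nitrogen. The growth description counts 3 batches, 1 per DO level, in triplicate. It leaves open whether the 3 libraries of a level came from separate fermentations, and p-values then measure only the spread between these samples. Libraries were made with the TruSeq kit. The submitters' processing notes name CASAVA without a version, and the aligner, the genome build and the strand setting were not given in the sources used here.

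The authors deposited 1 table per library with read counts per gene, the coding length in bases, the percentage of the gene covered and an RPKM value (reads per kilobase of gene and 1000000 reads of the library). Read counts per gene, described as unique reads per the file headers, were used for every test. The RPKM values deposited by the authors matched those recomputed from reads, length and library total in all 9 libraries, and served in alternatives and in the level filter below. The deposited coverage percentages were not used here. Genes without a read were absent from a library's table and were set to 0. Reads summed to the stated library total in 9 of 9 libraries, and no ribosomal or transfer RNA was listed. Totals ran from 12.1 to 15.3 M reads (M for 1000000) and the median gene had between 978 and 1697 reads per library, so counting error was small beside the spread between libraries for most genes. Of 2589 genes with reads, 2521 carried a locus tag of the reference assembly ASM1132v1, which was used for gene symbols and gene order alone, and 603 had a symbol there. Symbols shared by 2 genes were replaced by locus tags, and gap stands for gapA. The reference gave no symbol for ldhA, pqo, cydA, narG, sdhA, ptsG, ripA and katA, so these were not analysed here by name.

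Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with all 9 libraries in 1 fit and the DO level as the single term. The filterByExpr step with its minimum count of 10 kept 2569 genes and dropped 20. The common dispersion was 0.0386, a biological coefficient of variation of 19.6%. The 3 contrasts between DO levels and an F test over all 3 levels were each adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called changed. Expression levels are counts per 1000000 reads (CPM) with TMM scaling, as mean ± SD over 3 libraries. Fold changes come from the fit, and their SE is the log2 fold change divided by the square root of F. Gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of a contrast. Figures and summaries used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

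The comparisons, tests, thresholds, 24 gene lists, alternatives and the rule for named genes were chosen before the data were examined. Of 213 list members sought by symbol, 111 were matched and 102 were not, and 19 lists had the 4 measured members needed for a test. Of the matched members, 9 carried another symbol of the same gene in the reference and were matched by a locus tag fixed beforehand. Measured members are those matched in either way and with reads. Unmatched members, most of them without a symbol in the reference, may have reads under a locus tag, so the lists are partial. A list of transposases had no member among the tested genes. The rule named, per contrast, up to 10 rises and 10 falls, the largest by fold change. These had an adjusted p under 0.05, non-overlapping groups, a mean RPKM of 10 or more in the higher group and a gene symbol. As fixed beforehand, the rule also admitted a product other than hypothetical protein. That part was not applied, so genes without a symbol could not be named by the rule. It added up to 4 members of each list with the smallest p, and a fixed set of oxygen and central metabolism genes. Counts of changed list members are also given adjusted over the list alone. Genes named only by locus tag, such as NCgl1498, were picked after their values were seen, except those the rule named, NCgl0898, NCgl0573 and NCgl2621 among them. List members beyond the 4 of the rule were also picked after their values were seen. At 0% against 50% DO these were gdhA, leuC, ilvA, rplD, rplB, rpsS, rplV, rpmC and rpsQ, and at 0% against 30% DO rplP and rpsC.

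To see whether replicate numbers pair libraries across DO levels, each library's deviations from its group mean were correlated across genes with those of same-numbered libraries. The correlations between 30% and 50% DO were 0.31, 0.24 and 0.26 for replicates 1, 2 and 3. Differently numbered libraries of those levels ranged from -0.56 to 0.46. For 0% against 30% DO they were -0.06, 0.23 and 0.17, and for 0% against 50% DO 0.12, 0.20 and 0.01. A model with the replicate number as a block is therefore given beside the comparison of 30% with 50% DO.

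The pipeline was tested on simulated data in which 200 genes changed. At a 2-fold change it recovered 70.1% of genes for 0% against 50% DO, 83.6% for 0% against 30% DO and 83.6% for 30% against 50% DO. Recovery was 14.9%, 37.3% and 26.9% at a 1.5-fold change. Over all simulated changes together there were 5, 9 and 10 false calls. None (0) of the 19 unchanged lists was called. Each comparison had 1 simulation, in which a gene kept 1 dispersion in all 9 libraries and, apart from the change, 1 mean. Differences in recovery between comparisons therefore do not measure differences in their power. Real libraries were closer to each other within 0% DO (correlations of log2 CPM from 0.989 to 0.992) than within 50% DO (0.968 to 0.988). Simulated genes varied independently of each other, so the simulation cannot test lists whose members vary together. In the real libraries the estimated correlation was 0.914 for the iron-sulfur list at 0% against 50% DO.

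Alternatives were no filter, a stricter filter at a mean count of 50, median scaling by DESeq2 size factors, DESeq2 1.42.0 and a replicate block. Further ones were limma on log2 RPKM plus 1 with and without a trend and with quantile normalization, the 6 libraries of a contrast by themselves, an added 2-fold threshold, and each library left out in turn. Lost calls of single genes are given for the alternatives other than the 2-fold threshold, which ends each call under 2-fold. A replicate block fitted to the 6 libraries of a contrast was added after seeing the data. Changes of the RPKM pseudocount were not run, since the tests rest on counts.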

Results

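The series asked how the transcriptome of Corynebacterium glutamicum, a soil bacterium used to make amino acids, responds to a change in dissolved oxygen. RNA was sequenced from cultures at 0%, 30% and 50% DO, with 3 libraries at each level. The tables held 13.7, 12.1 and 12.9 M reads (M for 1000000) for 0% replicates 1 to 3. At 30% DO the totals were 14.2, 14.9 and 14.6 M reads, and at 50% DO 14.7, 15.3 and 14.5 M reads. Reads fell on 2589 genes, of which 2571 had reads in all 9 libraries, and the 10 most abundant genes took between 11.2% and 16.2% of a library. On the first principal component, which held 54.1% of the variance, the 0% libraries lay at -20.9, -22.9 and -24.8 and the other 6 libraries between 9.66 and 14.1. The second component, with 20.7%, placed 50% replicates 1 and 2 at 20.7 and 12.9 and 50% replicate 3 at -3.17, beside the 30% libraries at -5.03, -14.2 and -8.89.

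**Figure D1:**
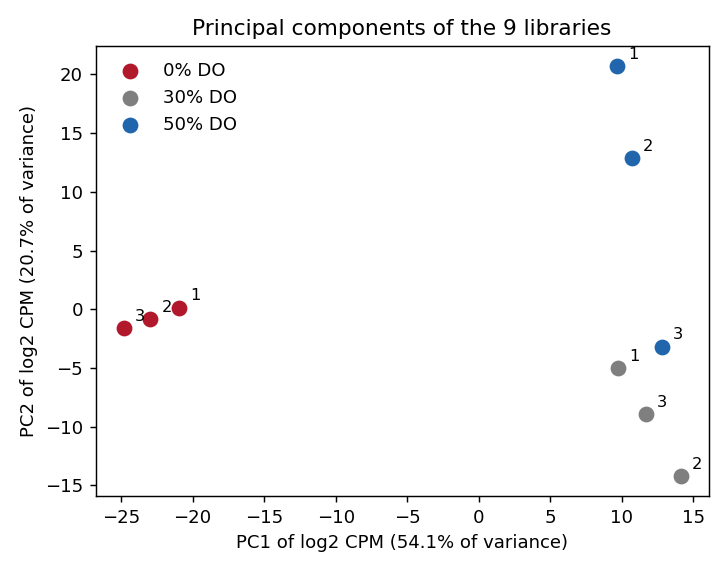
Principal components of log2 CPM for the 9 libraries, first component (54.1% of the variance) on the horizontal axis and second component (20.7%) on the vertical axis, 1 point per library coloured by DO level. The 3 libraries at 0% DO lie between -20.9 and -24.8 on the first axis, apart from the other 6 libraries, and 50% replicate 3 lies at -3.17 on the second axis, against 20.7 and 12.9 for the other 50% libraries.

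The comparison of 0% with 50% DO asked which genes respond to the lowest against the highest oxygen supply. Genes of the suf cluster, which assembles iron-sulfur clusters for proteins, fell furthest among the fixed lists. At 0% DO sufU was 13.2-fold lower (91.4 ± 19.2 against 1203 ± 346 CPM, n = 3 each), sufC 11.6-fold, sufD 9.89-fold and sufB 5.19-fold lower. Genes for tryptophan synthesis were higher at 0% DO, with trpA up 2.76-fold, trpCF 2.49-fold, trpB 2.02-fold and trpD 1.91-fold. Among respiratory genes, the cytochrome bd oxidase subunit cydB, part of an oxidase with high oxygen affinity, was 2.78-fold higher (331 ± 20.3 against 119 ± 52.4 CPM, adjusted p = 0.00193), and the nitrate reductase subunit narI was 3.49-fold higher (22.8 ± 6.52 against 6.56 ± 3.28 CPM, adjusted p = 0.00621).

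The log2 fold changes of sufU, sufC and sufD were -3.72 (SE 0.26, adjusted p = 1.28e-05), -3.54 (SE 0.27, adjusted p = 2.33e-05) and -3.31 (SE 0.35, adjusted p = 8.7e-05), and that of sufB was -2.38 (SE 0.44, adjusted p = 0.00213). All 4 members of the iron-sulfur list matched by symbol fell, as they did when adjusted over the list alone (adjusted p = 3.61e-09 for the list, adjusted p = 0.193 with an estimated correlation). The members sufR and sufS were not matched. The median log2 change of the 4 genes was -3.42 in the fit. Taken as differences of mean log2 levels (CPM, or RPKM for the last 2) it was -3.45 with TMM, -3.45 with median scaling, -3.37 with quantile scaling and -3.52 without scaling. All 4 measured tryptophan genes rose, also adjusted over the list alone (adjusted p = 0.000488 for the list, adjusted p = 0.193 with an estimated correlation).

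Nitrogen genes formed a further list that was lower at 0% DO. Of 8 measured genes of glutamate, glutamine and ammonium metabolism 5 fell, also 5 adjusted over the list alone (adjusted p = 0.0274 for the list, adjusted p = 0.193 with an estimated correlation). The members that fell were the glutamate uptake genes gluA (4.14-fold), gluB (4.4-fold) and gluC (2.03-fold), the glutamate synthase gene gltB (2.08-fold) and the glutamate dehydrogenase gene gdhA (1.93-fold). One library weighed on gluA and gluB, whose log2 changes of -2.05 and -2.14 became -1.41 and -1.28 without 50% replicate 1. Of 5 global regulators 3 fell and 1 rose, the same numbers when adjusted over the list alone (adjusted p = 0.0274 for the list, adjusted p = 0.353 with an estimated correlation). The sigma factor gene sigE fell from 5377 ± 502 to 1130 ± 174 CPM (4.76-fold, adjusted p = 3.39e-05). The acetate regulator genes went opposite ways, ramB lower by 3.25-fold (adjusted p = 6.79e-05) and ramA higher by 1.77-fold (adjusted p = 0.00452). The third fall was that of glxR (log2 -0.59, adjusted p = 0.0407), lost in 7 alternatives at adjusted p up to 0.149, among them those without any 1 of the 0% replicates, 30% replicate 2 or 50% replicates 1 or 2. The list calls for global regulators and for nitrogen metabolism were lost without 0% replicate 1, each at adjusted p = 0.0936, and that for nitrogen metabolism with the 6 libraries of the contrast by themselves (adjusted p = 0.0505).

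The remaining 15 tested lists missed the threshold as lists, while some of their members changed. Ribosomal protein genes split, with 13 of 50 higher and 8 lower at 0% DO, the same numbers adjusted over the list alone (adjusted p = 0.0549 for the list). Those lower were rplD, rplB, rpsS, rplV, rpsC, rplP, rpmC and rpsQ. All 8 lie close together, with locus tags from NCgl0488 to NCgl0496, so they may not be independent members. The calls of rplV, rplD, rpsS and rpsQ were lost in 7, 6, 3 and 2 alternatives (adjusted p up to 0.14, 0.145, 0.0822 and 0.0572), each among them without 0% replicates 1 and 3 in turn. The gene rplO showed the largest rise of the list (2877 ± 352 against 1122 ± 156 CPM, 2.56-fold). In the citric acid cycle the malate:quinone oxidoreductase gene mqo was the 1 of 6 measured genes to rise, by 2.53-fold (1999 ± 57.2 against 789 ± 67.9 CPM, adjusted p = 7.07e-05, with adjusted p = 0.0709 for the list). Among 8 glycolytic genes 4 fell (adjusted p = 0.194 for the list), with eno 2.05-fold lower (adjusted p = 0.00047). The falls of ptsP and pyk were lost in 12 and 14 of 19 alternatives, at adjusted p up to 0.205 and 0.176, among them those without any 1 of the 0% replicates. That of pgi was lost in 2, without 0% replicate 1 and after quantile normalization (up to 0.0942). Of 7 branched-chain amino acid genes 5 fell, leuD by 2.09-fold and leuC by 1.89-fold among them, and ilvA rose 1.42-fold (adjusted p = 0.233 for the list). The fall of ilvC, 1.55-fold, was lost without 0% replicate 1 (adjusted p = 0.0516). That of leuC was lost without 0% replicate 1 or 3 (adjusted p up to 0.0541), and the rise of ilvA without 0% replicate 2 and with limma on log2 RPKM (up to 0.08). In the aerobic respiratory chain list of 4 genes cydB rose and cydC fell 1.56-fold, and the cytochrome aa3 oxidase gene ctaD had a log2 change of 0.10 (adjusted p = 0.765; adjusted p = 0.75 for the list). At the pyruvate node the dehydrogenase gene aceE fell 2.15-fold (adjusted p = 0.00263) and lldD rose 2.41-fold (adjusted p = 0.00313), 2 of 5 measured genes (adjusted p = 0.981 for the list). The gene lldD is a lactate dehydrogenase gene other than ldhA, which was not analysed by name. The counts of this paragraph after the ribosomal genes did not change when adjusted over the list alone.

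Smaller counts stood in the other lists at 0% against 50% DO. Sulfur metabolism had cysD 1.8-fold higher and the methionine synthase gene metE 2.28-fold and its regulator gene mcbR 1.89-fold lower, out of 6 genes, with a median log2 change of 0.02 and a mean of -0.15. Arginine synthesis had 2 of 5 genes lower, argF at 1.8-fold and argC (log2 -0.62, call lost without 0% replicate 3 at adjusted p = 0.0567), and gndA was the 1 gene of 5 in the pentose phosphate pathway to fall, by 1.82-fold. One gene each changed in heat shock (grpE, 1.84-fold higher, of 8), lysine and threonine synthesis (dapB, 1.38-fold lower, of 10) and tRNA charging (1 higher of 17). Oxidative defence had msrA higher (log2 0.48, adjusted p = 0.0418) and mtr lower (log2 -0.54, adjusted p = 0.00727) of 6. The call of msrA was lost in 8 alternatives, at adjusted p up to 0.127, and that of mtr after quantile normalization (adjusted p = 0.0574). In edgeR 0 of 5 phosphate starvation genes passed (0 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma), and 0 of 5 ribonucleotide reduction genes (1 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma). The lists of sulfur, arginine, pentose phosphate, heat shock, lysine, tRNA, oxidative, phosphate and ribonucleotide genes had adjusted p between 0.204 and 0.965. The calls of mcbR, grpE and dapB were lost in 3, 2 and 2 alternatives, at adjusted p up to 0.102, 0.0709 and 0.0881. These counts, too, were the same adjusted over the list alone. A further 4 lists had from 1 to 3 measured members and were not tested. Nitrate respiration had 1 of 3 members higher, or 2 adjusted over the list alone, with log2 changes of 0.31 for narH (adjusted p = 0.223) and 0.69 for narJ (adjusted p = 0.0642), the latter called in 8 alternatives. Its members narK and narG had no symbol in the reference and are not in this count. ATP synthase had 0 of 3 called in edgeR, with 0 at an unadjusted p under 0.05 and 0 with DESeq2 or limma. The glyoxylate gene aceA was 3.15-fold lower (adjusted p = 0.0156, up to 0.0703 under alternatives; log2 -1.66, or -0.79 without 50% replicate 1), 1 of 2 in its list. The ferritin-like gene dps was lower with a log2 change of -1.49, the 1 member of the iron list matched by symbol.

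By fold change, the largest named rises besides those above were tctA of a tricarboxylate transporter (3.88-fold, adjusted p = 8.7e-05), benC of benzoate oxidation (3.51-fold), the inositol dehydrogenase gene iolG (2.74-fold), tilS (2.64-fold) and aztA (2.61-fold). Further large falls were the biotin synthesis gene bioD (3.37-fold) and the mechanosensitive channel gene mscL (3.11-fold). In all, 910 of 2569 genes (35.4%) passed the threshold at 0% against 50% DO, 425 higher and 485 lower, and 317 of them changed 2-fold or more. The 3 values of each group did not overlap for 1296 genes (50.4%), where chance gives 10%. The number of genes called was 585 without 0% replicate 3. The share of calls that were higher was 46.7%, against 37.4% with limma on log2 RPKM, where the median of all genes moved to -0.09 from -0.03, and 54.6% after quantile normalization.

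**Figure D2:**
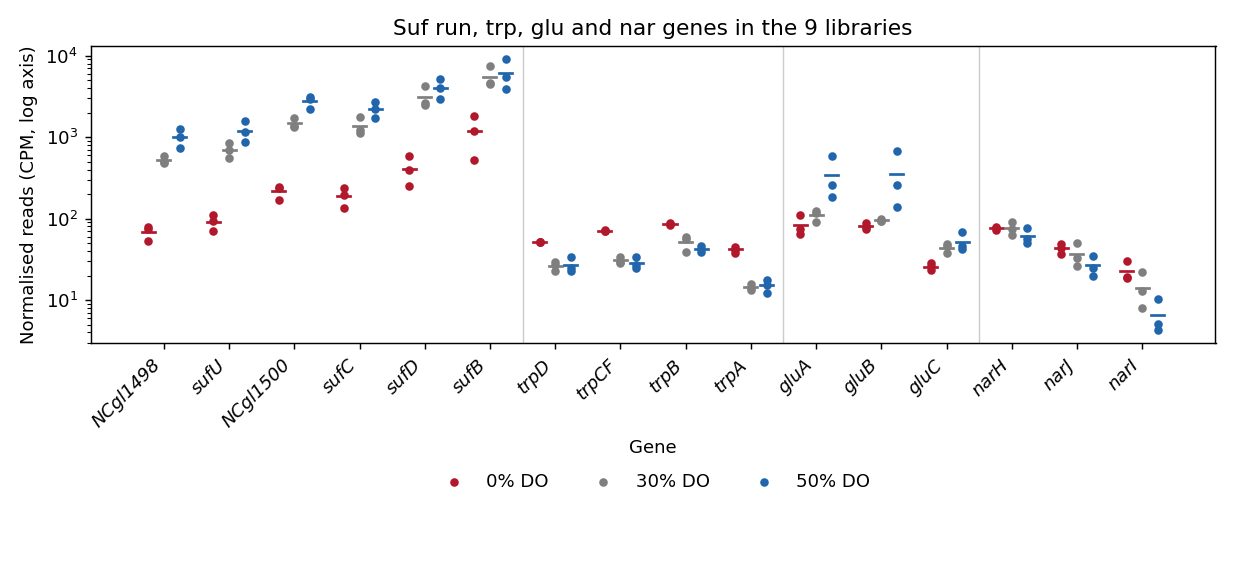
CPM (vertical log axis) of genes of the suf run, tryptophan synthesis, glutamate uptake and nitrate reductase at 0%, 30% and 50% DO, 1 point per library, with a line at each group's mean. The suf genes lie lower in the 0% libraries than in the other 6 (sufC means 190 CPM at 0% against 1365 and 2201 CPM at 30% and 50% DO), and trpCF lies higher (71.1 against 30.6 and 28.5 CPM).

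The comparison of 0% with 30% DO asked what separates the lowest from the intermediate oxygen level. The suf genes were again lower at 0% DO, sufU by 7.67-fold, sufD by 7.59-fold, sufC by 7.19-fold and sufB by 4.69-fold, and dps, which protects DNA and stores iron, was lower by 4.35-fold (510 ± 140 against 2219 ± 754 CPM, n = 3 each). Tryptophan genes were higher, with trpA up 2.91-fold, trpCF 2.32-fold, trpD 1.96-fold and trpB 1.66-fold. Of 8 glycolytic genes 4 were higher at 0% DO, tpiA 2.23-fold, gap 1.6-fold, pyk 1.58-fold and pgk 1.49-fold. The malate synthase gene glcB was 3.81-fold higher (1365 ± 479 against 358 ± 42.2 CPM).

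At 0% against 30% DO the log2 changes were -2.94 for sufU (SE 0.25, adjusted p = 3.6e-05), -2.85 for sufC (SE 0.27, adjusted p = 5.73e-05) and -2.12 for dps (SE 0.28, adjusted p = 0.000303). Both called lists had all 4 members changed, also adjusted over the list alone. They were the iron-sulfur list (lower, adjusted p = 1.44e-06, adjusted p = 0.362 with an estimated correlation) and the tryptophan list (higher, adjusted p = 0.00237, adjusted p = 0.362 with an estimated correlation). The suf median was -2.89 in the fit and, as differences of mean log2 levels, -2.90 with TMM, -2.89 with median scaling, -2.88 with quantile scaling and -2.99 without scaling. The other 17 tested lists missed the threshold, glycolysis at adjusted p = 0.251 with 4 of 8 higher, also 4 adjusted over the list alone. The rises of pyk, pgk and gap were lost in 4, 6 and 7 of 19 alternatives, at adjusted p up to 0.0711, 0.133 and 0.124.

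Nitrogen genes at 0% against 30% DO had 4 of 8 members lower, also 4 adjusted over the list alone (adjusted p = 0.152 for the list). These were gltB (2.95-fold), the glutamine synthetase gene glnA (1.92-fold), gdhA (1.76-fold, adjusted p up to 0.0553 under alternatives) and gluC (1.71-fold). Ribosomal protein genes had 12 of 50 higher and 9 lower, the same numbers adjusted over the list alone (adjusted p = 0.35 for the list). The gene rplO was 3.05-fold higher, while rplB, rplP and rpsC were 3.17-, 3.01- and 2.63-fold lower. Regulator genes included sigE, 3.85-fold lower, ramB, 2.86-fold lower, and ramA, 2.04-fold higher (adjusted p = 0.152 for the list of 5). Branched-chain amino acid genes had 2 higher and 2 lower of 7, ilvA 2.21-fold higher and leuD 2.2-fold lower among them (adjusted p = 0.817 for the list). In respiration cydB was 2.01-fold higher (adjusted p = 0.0119) and cydC 2.03-fold lower (adjusted p = 0.000375), while narI had a log2 change of 0.68 (adjusted p = 0.18) and was called in 3 alternatives, with a replicate block in 9 or in 6 libraries and without 30% replicate 3 (log2 1.14). The gene mqo was 2.24-fold higher and aceE 1.93-fold lower (adjusted p = 0.00526). Values for aceA, lldD and ctaD were 0.32 (adjusted p = 0.587), 0.30 (adjusted p = 0.349) and 0.24 (adjusted p = 0.467) on the log2 scale. Thiol defence had trxB 1.91-fold higher, 3 of 6 members higher in all (adjusted p = 0.572 for the list), and tRNA charging had trpS, serS and tyrS higher, by 1.8-, 1.62- and 1.71-fold (adjusted p = 0.336 for the list). For these lists the counts were the same adjusted over the list alone, and heat shock went from 2 higher of 8 to 4. The calls of ilvD, whcA and grpE in these lists were lost in 1, 7 and 2 alternatives, at adjusted p up to 0.0572, 0.136 and 0.068. Median, mean and test differed in sign for the branched-chain, lysine and threonine, ribonucleotide and sulfur lists, all with adjusted p from 0.686 to 0.977.

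Other large named changes at 0% against 30% DO were rises of tctA (4.65-fold), benC (3.76-fold), iolG (3.53-fold), secG of protein export (3.27-fold), whiA (3.01-fold), the heme synthesis gene hemQ (2.56-fold) and rsmG (2.47-fold). Further falls were bioD (3.63-fold), NCgl0898, 1 of 2 genes with the symbol pth (3.24-fold), and cmr (3.2-fold). In all, 1044 of 2569 genes (40.6%) passed the threshold, 490 higher and 554 lower, and 346 changed 2-fold or more. Groups did not overlap for 1455 genes (56.6%), where chance gives 10%. The share of calls that were higher was 46.9%, against 36.4% with limma on log2 RPKM, where the median of all genes moved to -0.12 from -0.03, and 54.7% after quantile normalization.

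The comparison of 30% with 50% DO asked whether an intermediate oxygen level differs from a high one. Glycolytic genes were lower at 30% DO, with pyk lower by 2.27-fold (1042 ± 93.9 against 2369 ± 633 CPM, n = 3 each), gap by 2.18-fold, tpiA by 2.1-fold, pgk by 1.8-fold, and pgi and eno by 1.75-fold. The ribosome hibernation gene hpf was 3.12-fold lower and the lysine exporter gene lysE 1.79-fold lower. The branched-chain amino acid genes ilvN, ilvC and ilvA were 1.93-, 1.64- and 1.56-fold lower. The glutamate uptake genes gluB and gluA were 3.72- and 3.12-fold lower and the isocitrate lyase gene aceA 3.93-fold lower.

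For pyk, hpf and lysE the log2 changes were -1.19 (SE 0.19), -1.64 (SE 0.28) and -0.84 (SE 0.14), each with adjusted p = 0.0177, and for gap -1.12 (SE 0.23, adjusted p = 0.0345). Of 8 glycolytic genes 6 fell, or 7 adjusted over the list alone (adjusted p = 2.18e-08 for the list, adjusted p = 0.295 with an estimated correlation). Of 7 branched-chain genes 3 fell, also 3 adjusted over the list alone (adjusted p = 0.00543 for the list, adjusted p = 0.295 with an estimated correlation). In the pentose phosphate pathway 1 of 5 genes fell, gndA by 1.68-fold, or 3 adjusted over the list alone (adjusted p = 0.00618 for the list, adjusted p = 0.295 with an estimated correlation). The branched-chain and pentose phosphate calls were lost without 30% replicate 3, each at adjusted p = 0.0551. The seryl-tRNA synthetase gene serS was 1.67-fold lower, the 1 of 17 in its list. Iron-sulfur genes had 0 of 4 called in edgeR, or 2 lower adjusted over the list alone (2 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma; adjusted p = 0.164 for the list). Tryptophan genes had 0 of 4, also adjusted over the list alone (0 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma; adjusted p = 0.763 for the list). Of 50 ribosomal protein genes 0 passed, also adjusted over the list alone (5 at an unadjusted p under 0.05, 2 with DESeq2 and 0 with limma; adjusted p = 0.216 for the list). The heat shock list had a median log2 change of -0.05 and a mean of 0.03 (adjusted p = 0.971). For lldD the log2 change was 0.97 (adjusted p = 0.0566, called with DESeq2 and without 50% replicate 3), for aceE -0.16 (adjusted p = 0.675) and for ctaD -0.13 (adjusted p = 0.765).

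High values in 1 library carried part of the 30% against 50% DO differences. Without 50% replicate 1 the log2 changes of aceA, gluB and gluA went from -1.98, -1.90 and -1.64 to -1.12, -1.05 and -1.01 and their calls were lost. In all, 73 of 2569 genes (2.8%) passed the edgeR threshold, 11 higher and 62 lower at 30% DO, with 26 changed 2-fold or more. Groups did not overlap for 637 genes (24.8%), where chance gives 10% if the 6 libraries are exchangeable. The share that chance gives under a pairing by replicate number was not computed. With the replicate number as a block 115 genes passed in all 9 libraries and 6 in the 6 libraries of the contrast, the latter fit added after seeing the data. The share of calls that were higher was 15.1%, against 30.9% with DESeq2 and 44.4% of 27 calls after quantile normalization. DESeq2 called 301, limma on log2 RPKM 10 with a trend and 0 without (563 at an unadjusted p under 0.05). The 6 libraries by themselves gave 0 with edgeR (505 at an unadjusted p under 0.05), and leaving out single libraries gave from 0, without 30% replicate 1 or 2, to 453, without 50% replicate 3. None (0) of the 18 named genes called kept its call in every alternative.

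**Figure D3:**
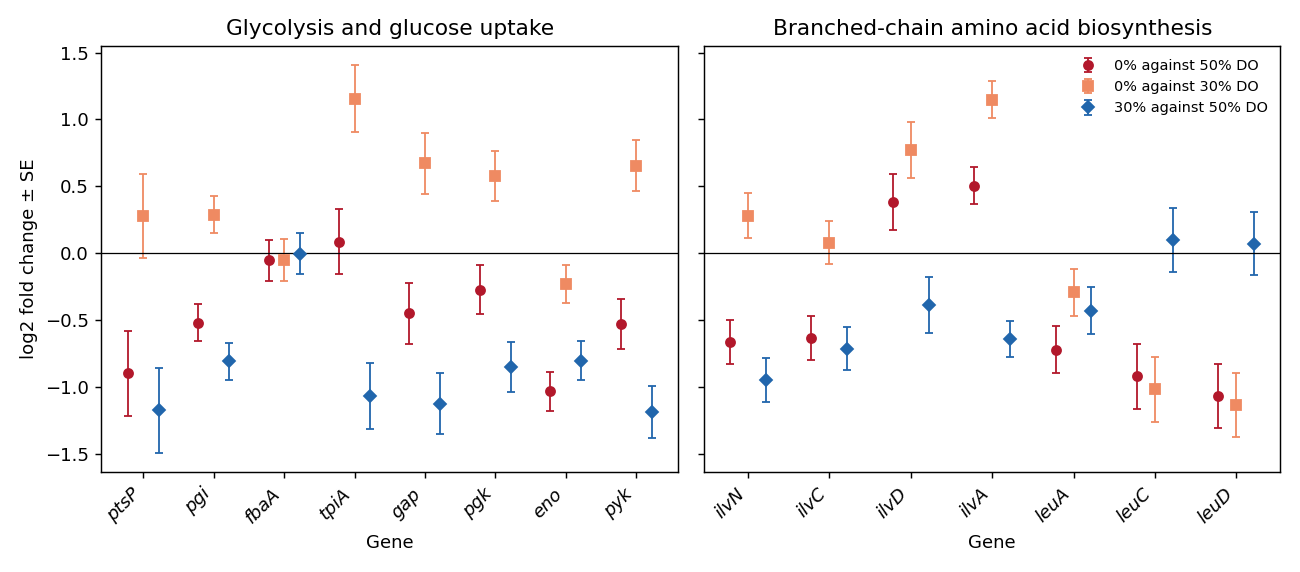
Log2 fold change (vertical axis, ± SE) of each measured gene of the glycolysis list (left) and of the branched-chain amino acid list (right), with 1 symbol per comparison of DO levels. Of 8 glycolytic genes 6 passed the test at 30% against 50% DO, all below 0, and at 0% against 30% DO the 4 that passed lie above 0.

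The test over all 3 DO levels asked which genes vary with oxygen at all. The sigma factor gene sigE averaged 1130, 4352 and 5377 CPM at 0%, 30% and 50% DO (adjusted p = 6.75e-05), sufU 91.4, 701 and 1203 CPM (adjusted p = 2.66e-05) and sufC 190, 1365 and 2201 CPM (adjusted p = 5.21e-05). In the other direction mqo averaged 1999, 891 and 789 CPM (adjusted p = 7.55e-05) and trpCF 71.1, 30.6 and 28.5 CPM (adjusted p = 0.000167). The genes tpiA and gap had their lowest mean at 30% DO, tpiA with 141, 63.2 and 132 CPM (adjusted p = 0.0073) and gap with 1506, 944 and 2058 CPM (adjusted p = 0.00773). For ctaD the means were 7758, 6588 and 7217 CPM (adjusted p = 0.694). In all, 1169 of 2569 genes (45.5%) passed, and 738 did so without 0% replicate 3. The count filter left out 20 genes.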

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

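The tests of a step shared by the 0% libraries and of gene order were chosen only after the result was seen. Some genes too thinly covered to be tested had reads at 0% DO and none in the other 6 libraries, a signal outside the comparisons. Summed over the 0% libraries, NCgl2373 had 49 reads, NCgl2374 28, NCgl2377 27, NCgl2376 26 and NCgl2372 22. These 5 had reads in all 3 libraries at 0% DO. NCgl1291 had 6 reads and NCgl0127 4, all from 0% replicate 3, and NCgl2832 had 5, with 0, 2 and 3 in replicates 1 to 3. NCgl2375, between NCgl2374 and NCgl2376, passed the count filter with 30, 12 and 59 reads at 0% DO and 0 of 88.3 M reads (M for 1000000) in the other libraries. Against a floor of 3 counts over those 6 libraries together it was at least 77.1-fold higher, or at least 48-fold without 0% replicate 3, bounds that cover counting error only. Whether these genes were silent at 30% and 50% DO or absent from the strain grown there stays open, since no genome sequence of the cultures was at hand. The source of their few reads at 0% DO was not tested either.

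The first pattern is the number of genes that differ between 0% and 50% DO, 910 in edgeR. The tables argue against lower depth of the 0% libraries as the whole cause, since 98.2% of the calls remained with every library thinned to the lowest total. A trend with coding length is argued against in the same way, with 93% of calls remaining after a smooth length trend was removed from each library. A batch or sampling step shared by the 0% libraries cannot be told apart from the DO level, because the tables of those 3 libraries carry a suffix that 0 libraries of the other groups share and the growth description gives 1 batch per level. A biological response to the DO level stays open beside it, untested on its own.

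The second pattern is the position of 50% replicate 3. On 200 genes that best separated 30% from 50% DO without it, it lay 0.73 of the way from its own group to the 30% libraries, with 147 genes nearer those. A wrong label on this 1 library stays open, since 0.73 lies between the bound of 0.5 set against it and the 0.8 set for it. On suf genes, looked at after their values were seen, it lay above the 30% libraries, as its label gives. It had 1567 CPM of sufU against 562 to 838 CPM at 30% DO, and 2683 CPM of sufC against 1138 to 1750 CPM, with 1165 and 2198 CPM in the next-highest 50% library. So few genes do not exclude a wrong label. Across all genes tested, 50% replicate 3 correlated most with 30% replicate 3 (r = 0.988 on log2 CPM), against 0.968 and 0.978 with 50% replicates 1 and 2. With 30% replicates 1 and 2, 30% replicate 3 correlated at 0.982 and 0.981. A swap with a 30% library needs a partner out of place. The highest 30% library, replicate 3, lay 0.44 of the way to the mean of the 50% libraries, 50% replicate 3 included. That meets the bound of 0.5 by less than the spread between the 30% libraries (SD 0.25), so the swap stays open too, and no biological explanation was tested.

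Other splits of the libraries were tested for each comparison. Splitting 3 libraries against 3 gives 10 splits, too few for a share under 0.05. For 0% against 50% DO 1 of 10 splits gave as many genes, the real one with 910, and the highest other gave 0. For 0% against 30% DO 1 of 10 did, the real one with 1044, and the highest other gave 0. For 30% against 50% DO 1 of 10 did, the real one with 73, and the highest other gave 66. That other split set 30% replicate 1 with 50% replicates 1 and 2, against the rest, and parts 1 same-numbered pair. The 3 other splits that part all 3 pairs, as the real one does, gave 0 genes. For gene lists 4 of 10 splits gave as many in each comparison, with real counts of 4, 2 and 3 and highest others of 5, 2 and 7. For the test over all 3 levels 1 of 100 drawn splits gave as many, the real one with 1169 genes against 896 for the highest other. Chance assignment of all 9 libraries is argued against there, which does not cover chance assignment between 30% and 50% DO alone. If the 3 libraries of a level came from 1 fermentation, such splits cannot exclude chance differences between fermentations. The next-highest splits, with 896, 744 and 647 genes, kept the 0% libraries together, which points to a structure of the samples that separates those 3.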

How the results depend on the processing

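The 2 comparisons with 0% DO kept their counts within 1.5 times under all alternatives except the added 2-fold threshold, which by construction lowers 910 to 317 and 1044 to 346, and 1 left-out library. Leaving out single libraries gave 585 to 967 genes for 0% against 50% DO, 730 to 1180 for 0% against 30% DO and 738 to 1418 for the test over all levels. The lowest counts, 585 in place of 910 and 738 in place of 1169, both came without 0% replicate 3. Without 50% replicate 3 these counts were 913 and 1418, but that library lay apart from its group, so it is no control for having fewer samples. Leaving out 0% replicates 1 and 2 also lowered the counts, to 714 and 666 for 0% against 50% DO and to 872 and 785 for all levels. Whether the loss of a library accounts for the drop without 0% replicate 3 stays open. For 30% against 50% DO the 73 genes became 115 with a replicate block, 301 with DESeq2 and 10 with limma with a trend. They became 0 with limma without a trend (563 at an unadjusted p under 0.05), 27 after quantile normalization and 26 with the 2-fold threshold. The 6 libraries by themselves gave 0 in edgeR (505 at an unadjusted p under 0.05) and, with a block added after seeing the data, 6. Left-out libraries gave 0 to 453 there. Counts were 37, 26 and 18 without 0% replicates 1, 2 and 3, and 0, 0 and 104 without 30% replicates 1, 2 and 3. They were 18, 18 and 453 without 50% replicates 1, 2 and 3. Of the 104 calls without 30% replicate 3, 48 were among the 73, and 38.5% of the 104 were higher at 30% DO, against 15.1% of the 73. At an unadjusted p under 0.05 the edgeR fits without 30% replicates 1 and 2 held 522 and 452 genes. All 9 libraries shared 1 estimate of spread per gene, so the 73 calls depend partly on the 0% libraries, which lie outside this contrast. Correlations of log2 CPM between libraries were 0.989 to 0.992 within 0% DO, 0.981 to 0.989 within 30% DO and 0.968 to 0.988 within 50% DO. Whether the shared spread is too small for 30% and 50% DO was not tested, nor, apart from thresholds, was another cause. With an estimated correlation camera called 0, 0 and 0 lists in place of 4, 2 and 3 (3, 2 and 2 at an unadjusted p under 0.05). Left-out libraries gave 2 to 5, 2 to 2 and 1 to 4 lists, with 2 without 0% replicate 1 and 1 without 30% replicate 3.

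No called gene changed sign under the alternatives run. Of the named genes called, 54 of 72 kept their call in every alternative other than the 2-fold threshold for 0% against 50% DO, 55 of 73 for 0% against 30% DO and 0 of 18 for 30% against 50% DO. With that threshold included the numbers were 44, 37 and 0. Direction reversed for uncalled values only, all with a library left out. For ctaD the log2 change ran from -0.012 to 0.273 at 0% against 50% DO, around 0.10, and from -0.331 to 0.057 at 30% against 50% DO, around -0.13. For aceE at 30% against 50% DO it ran from -0.314 to 0.105, around -0.16. The cause was not tested. Depth limits genes with few reads, of which 20 were left out of the tests. With all libraries thinned to the lowest total 909 genes were called at 0% against 50% DO, in place of 910.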

Other observations

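The test of gene order was chosen only after the result was seen, and the genes named in this part were picked after their values were seen. The suf genes lie in a run of 7 neighbouring genes, from NCgl1497 to sufB in the reference order, which all fell 2-fold or more at 0% against 50% DO. Its unnamed members NCgl1498 and NCgl1500 fell 14.5-fold (68.9 ± 13.5 against 999 ± 256 CPM, n = 3 each) and 12.6-fold (218 ± 42.6 against 2741 ± 447 CPM), each with adjusted p = 3.54e-06. At 0% against 30% DO they fell 7.62-fold and 6.76-fold, each with adjusted p = 3.14e-05. Another run of 6, from NCgl0930 to the enolase gene eno, held NCgl0933, which fell 17.4-fold at 0% against 50% DO (46.1 ± 5.38 against 803 ± 521 CPM, adjusted p = 6.8e-05; log2 -4.12, or -3.47 without 50% replicate 1). Beside it NCgl0932 fell 12-fold (log2 -3.58, or -2.96 without 50% replicate 1; adjusted p = 0.000211). At 30% against 50% DO they were 3.79-fold and 5.3-fold lower (adjusted p = 0.0266 and 0.0177), calls lost in 11 and 5 of 19 alternatives at adjusted p up to 0.13 and 0.113. Without 50% replicate 1 their log2 changes of -1.92 and -2.41 became -1.28 and -1.79. NCgl0251 fell 7.2-fold at 0% against 50% DO (adjusted p = 3.39e-05).

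Among unnamed genes that rose at 0% against 50% DO, NCgl2740 was 8.17-fold higher (1935 ± 1296 against 237 ± 45.7 CPM, adjusted p = 0.00114) and NCgl0334 6.92-fold higher (1752 ± 178 against 253 ± 55.6 CPM, adjusted p = 3.39e-05). NCgl1143 and NCgl1142, next to the nitrate reductase gene narH in the reference order, were 6.6-fold (1014 ± 207 against 153 ± 14.9 CPM) and 3.89-fold higher. The nitrate list members narK and narG had no symbol in the reference, and whether they are NCgl1143 and NCgl1142 was not settled here. A run of 5 genes ending at the molybdenum cofactor gene moaC rose between 2.18- and 5.52-fold. Runs of 3 neighbours rose around tctA, iolG and the tryptophan genes trpCF, trpB and trpA, and runs of 3 fell at gluA, gluB and gluC, at the ribosomal genes rpsC, rplP and rpmC, and at bioD with NCgl2517 and NCgl2518.

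The third pattern is that neighbouring genes changed together. At 0% against 50% DO 70 genes that changed 2-fold or more stood in 19 runs of 3 or more neighbours of 1 direction, 13 falling and 6 rising. With the gene order shuffled 9999 times the median was 3 genes and the highest 22, a permutation p of 1e-04, the smallest these shuffles can give. An order of genes that is random with respect to the change is thereby argued against, and shared transcription units are a candidate explanation that was not tested on its own. At 0% against 30% DO 58 genes stood in 16 runs (highest shuffled 23), and at 30% against 50% DO 0 did.

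Of 2826 protein-coding genes of the reference, 324 had no read in any library, and the longest run of such genes held 184, from NCgl1611 to NCgl1816. In 13 genes reads appeared in the 0% libraries alone, and 6 of these are neighbours, from NCgl2372 to NCgl2377, while 0 genes had reads in the other 6 libraries and none at 0% DO. Why a gene had no reads was not tested. The counts do not separate a silent gene from one absent from the strain. They hold unique reads only, and the authors' genome build was not given, so other reasons are not excluded. It also stays open whether the strain, or that at 0% DO alone, differs from the labelled ATCC 13032. Of 38 groups of genes with the same symbol stem, 2 passed camera at 0% against 50% DO (suf and trp), 2 at 0% against 30% DO (suf and trp) and 1 at 30% against 50% DO (ilv), and 0 passed with an estimated correlation.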
